A study of Arabidopsis thaliana with 3 samples.

How the data were processed

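Hi-C libraries of aerial tissue from 14-day-old Arabidopsis thaliana seedlings were analysed, with 1 sample each of Columbia wild type, plants homozygous for crwn1-1 and plants homozygous for crwn4-1. The deposited files, 6 per library, list pairs of genome windows of 10, 25, 50, 100, 200 or 250 kb with the count of read pairs that join them. These counts are raw and not normalised, as their whole-number values show. Reads were mapped to TAIR10 with Bowtie 0.12.7, per the submitters' processing notes. Further filters on reads, the removal of repeated read pairs and any pooling are not given in the sources used here. A tag in the file names may stand for reads or for replicates, so each sample, treated as 1 library, may hold pooled replicates that cannot be separated.

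Windows carry numbers without chromosome names. They were taken to run through chromosomes 1 to 5, a layout inferred here and checked in 3 ways. The number of windows fitted chromosome lengths bounded by the last gene of each chromosome at each of the 6 sizes. Where these bounds left 2 choices, the highest window number decided, so this fit is partly set by the files. A total also cannot test the order of the chromosomes. The 100 kb list of each library equalled the sum of its 10 kb list. Mean counts across the numbered chromosome borders were 0.117 to 0.587 times the genome median at equal distance. This check is weak for the borders before chromosomes 3 and 5, where up to 20.1% of positions were as low, and stronger for those before chromosomes 2 and 4 (at most 3.30%). Totals were 16291506 read pairs in wild type, 44744537 in crwn1 and 36508909 in crwn4.

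Counts were more dispersed in the mutant libraries. Between arms of different chromosomes, the variance of 10 kb counts over their mean was 1.14 in wild type, 3.22 in crwn1 and 5.15 in crwn4. Independent read pairs give a value of 1 if all window pairs have the same expected count, and a higher value if they do not. Read pairs divided by the variance over mean came to 14245799 in wild type, 13880033 in crwn1 and 7094831 in crwn4. Intervals of contacts (95%, exact Poisson, or normal on the log scale for ratios and for single windows) and of the share of counts within chromosomes (Wilson) use counts divided by it. Intervals for shares of windows are Clopper-Pearson and treat windows as independent, which neighbouring windows are not. Intervals cover counting error only, not variation between plants or libraries. The variance over mean was measured between arms, so intervals may be too narrow for classes where counts repeat more.

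The main setting was 100 kb windows. Windows with under 20% of the median sum were left out, which kept 1176, 1173 and 1171 of 1193 windows in wild type, crwn1 and crwn4. Each matrix was corrected iteratively to equal window sums without its diagonal. Contacts between chromosomes were divided by the library's mean over arm windows of different chromosomes. Contacts within chromosomes were divided by the mean at equal distance. These ratios, called observed over expected, were computed here from the deposited counts. Pericentromeres were taken as 1.5 Mb on each side of the centromere midpoint (15, 3.6, 14, 4 and 12 Mb on chromosomes 1 to 5), chromosome ends as the terminal 0.5 Mb, and the knob of chromosome 4 as 1.6 to 2.3 Mb. The decay exponent is the slope of log10 contact on log10 distance from 0.2 to 3 Mb within arms over 5 Mb long. Compartments are signs of the first eigenvector per arm with at least 20 windows, oriented by gene number.

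Long-range elements were called in wild type as arm windows with at least 4 partner loci that each had at least 10 counts and an observed over expected of at least 2.5. Partners lay on another chromosome or over 2 Mb away. A stricter rule was added after seeing the data: the contact had to be at least 3 times the mean of the ring 0.2 to 1 Mb around it, in each of the 3 libraries. Windows called in crwn4 but not in all 3 libraries are not read as loci. Rearrangements were sought as window pairs on different chromosomes or over 5 Mb apart, with at least 10 counts and at least 5 times the contact of both other libraries. Counting those with at least 2 such neighbours was added after seeing the data.

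The 86 genes of 4 gene lists were all matched by locus identifier. Their contacts were summed in 25 kb windows, between chromosomes and over 100 kb apart on an arm, and ranked among 10000 random lists matched on chromosome arm. Local contact density is the contact at 20 to 100 kb of the 10 kb window of a gene, over the mean of arm windows. Genes in the same 10 kb window have the same density and each counts in the median of a list, and genes in windows left out of a library are missing there. Gene names and gene places come from a RefSeq table of TAIR10.1, used for names and for assigning genes to windows. No coordinates of that table are printed, and positions given are those of the deposited windows on TAIR10.

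Genes were named by a rule set before the data were examined: the 4 CRWN loci, up to 3 genes at the peak 10 kb window of an element, the 3 highest and 3 lowest genes of each list by local density or by change, and up to 2 genes in the 3 windows of largest change each way. The text gives a part of the list genes so chosen. For elements, the rule was applied to the loci of the stricter rule. The comparisons and their measures, the window classes, the gene lists and most alternatives were also fixed then; the tests of explanations were not. With 1 library per genotype no test between genotypes was possible and no p-value is given. Differences describe these libraries.

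Scripts ran in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Some of the measures were tested on simulated data in 5 runs of 1176 windows, with copied read pairs in 1 of 2 libraries. A planted pericentromere ratio of 1.5 came back as 1.44 and an unplanted telomere ratio as 0.998. At the depth of crwn1, all 9 planted loci were found in each run with 0 other windows. At the depth of wild type the library with copies gave all 9 but also 327.8 other windows per run, so calls from 1 shallow library with copies are unreliable. The loci reported are those called in all 3 libraries, a requirement that the simulation did not test. The depth of the simulation was raised after that first outcome. For the counts, the planted variance over mean of 3.89 came back as 4.09, measured from differences between neighbouring 100 kb windows. The variance over mean of 10 kb counts that scales the intervals is computed in another way and was not simulated. Alternatives covered the correction, window size, coverage filter, depth, pericentromere width, thresholds, distances, repeated counts and windows of very high coverage.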

Results

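Hi-C, which ligates and sequences DNA fragments that lie close together in the nucleus, was used on aerial tissue of 14-day-old Arabidopsis seedlings. Wild type was set against plants homozygous for crwn1-1 and for crwn4-1. CRWN1 and CRWN4 are lamina-like proteins of the plant nuclear periphery, and the comparison asks how chromosome contacts look without each of them. There was 1 deposited set of counts per genotype, taken as 1 library, of 16291506 read pairs in wild type, 44744537 in crwn1 and 36508909 in crwn4, so differences below are between libraries and none has a replicate check. Counts per window pair were higher in the mutant libraries than their depth gives for independent read pairs: a listed pair of 10 kb arm windows on different chromosomes held 1.13 counts on average in wild type, 2.37 in crwn1 and 3.51 in crwn4.

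**Figure D1:**
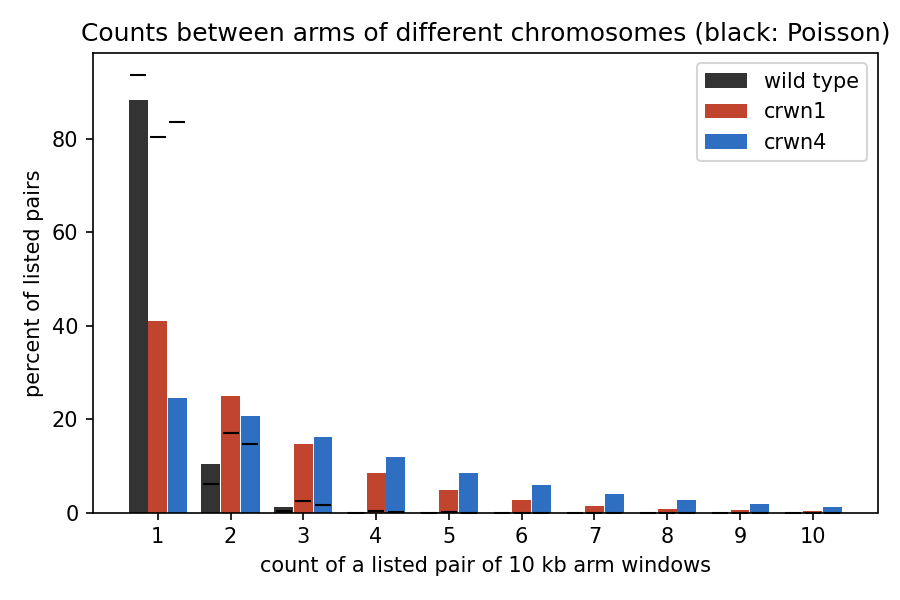
Percent of listed pairs of 10 kb arm windows on different chromosomes (vertical axis) that hold 1 to 10 counts (horizontal axis), as bars per library. Black marks are independent (Poisson) counts if each pair had the mean of its library. Pairs with 1 count made up 88.3% in wild type, 41.1% in crwn1 and 24.5% in crwn4.

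The CRWN1 gene itself took part in contacts in the crwn1 library that the other libraries lacked. The window holding CRWN1 (AT1G67230; chromosome 1, 25100001 to 25200000, TAIR10) met the locus at 22.5 to 22.7 Mb of chromosome 3 at 6.03 times the expected contact in crwn1 (95% counting interval 4.97 to 7.31, 332 read pairs). The value was 0.645 in wild type (0.360 to 1.15, 13 read pairs) and 0.269 in crwn4 (0.0886 to 0.818, 16 read pairs). Contact was lower on both sides of CRWN1, at 3.8 and 3.29 in the windows next to it and 2.38 and 2.3 in the following ones. Farther out, crwn1 was mostly near 1 but still above wild type in nearly every window starting at 23.6 to 26.6 Mb. Examples are 1.05 against 0.313 at 23.6 Mb and 1.21 against 0.438 at 25.9 Mb, with 26.4 Mb the other way (0.711 against 0.848). The cause of this wider difference was not tested. Within 0.5 Mb of the gene, the 10 kb window that holds CRWN1 (25150001 to 25160000) had the most read pairs with this locus in crwn1, 59 against a median of 10.

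The same window of the crwn1 library also met pericentromeres of other chromosomes more often. Its observed over expected was 1.81 in crwn1 (1.73 to 1.89), 0.777 in wild type (0.725 to 0.833) and 0.838 in crwn4 (0.767 to 0.915). Of 984 arm windows, it had the highest ratio of crwn1 to the higher other library for pericentromeres (2.16). The same held for the long-range loci described below (2.38), but these include the chromosome 3 locus. That locus held 332 of their 895 read pairs with the CRWN1 window in crwn1, so the 2.38 partly repeats its contact. A rank without that locus was not computed. For the chromosome 3 locus alone, 3 of 789 arm windows, CRWN1 included, had a ratio as high as its 9.35. That contact came out of the search for rearrangements described below, so this rank is not a separate check of it. Single partners included 4 to 4.1 Mb of chromosome 4 (7.40, against 1.23 in wild type), 13.5 to 13.6 Mb of chromosome 3 (4.47, against 0.797) and the first 100 kb of chromosome 2 (5.34, against 0.444).

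CRWN4 (AT5G65770; chromosome 5, 26300001 to 26400000) was not set apart in the same measures in the crwn4 library. Its contact with the chromosome 3 locus was 1.72 in crwn4 (1.05 to 2.81), 0.835 in wild type (0.529 to 1.32) and 1.46 in crwn1 (1.02 to 2.1), and 101 of 789 arm windows had as high a ratio of crwn4 to the higher other library. With pericentromeres of other chromosomes it was 0.410, 0.391 and 0.367 in crwn4, wild type and crwn1. Its single partners with the largest ratios to the higher other library were 21.2 to 21.3 Mb of chromosome 1 (1.73, against 0.154 in wild type, 30 read pairs), 1.6 to 1.7 Mb of chromosome 4 in the knob (1.68, against 0.418, 31 read pairs) and 3.1 to 3.2 Mb of chromosome 4 (1.97, against 0.542, 30 read pairs). CRWN2 (AT1G13220) had 0.866 with the chromosome 3 locus in crwn1 and 1.55 in wild type. CRWN3 (AT1G68790), which lies 7 windows from CRWN1, had 1.34 in crwn1 (0.931 to 1.92) and 0.497 in wild type (0.272 to 0.911).

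**Figure D2:**
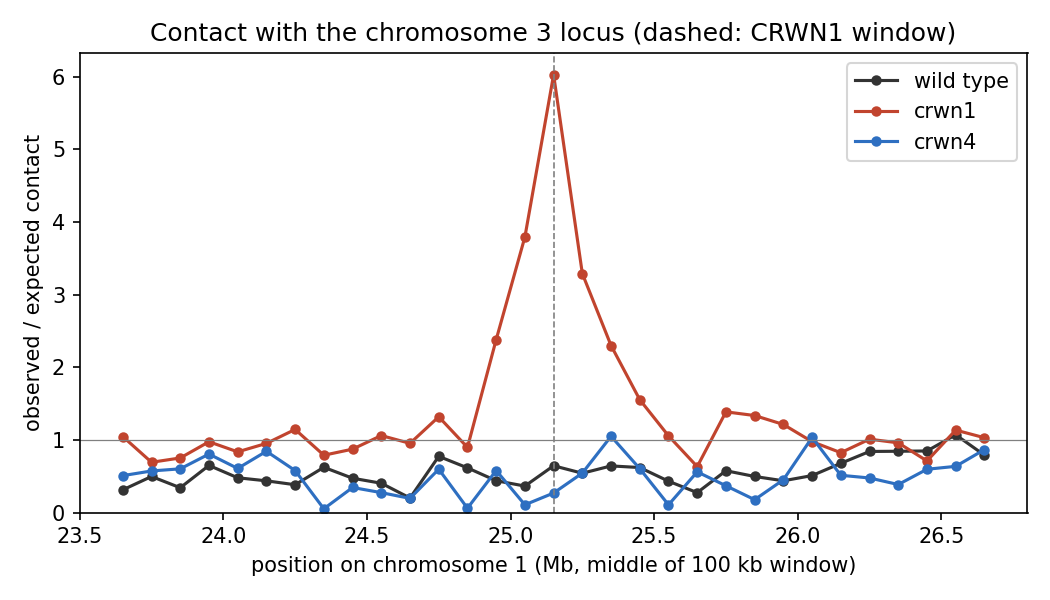
Observed over expected contact (vertical axis) of 100 kb windows along chromosome 1 (horizontal axis, Mb) with the locus at 22.5 to 22.7 Mb of chromosome 3, 1 line per library; the dashed line marks the window of CRWN1. The crwn1 line peaks at 6.03 in that window, where wild type is at 0.645 and crwn4 at 0.269.

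These contacts came out of the search for rearrangements. Window pairs with at least 5 times the contact of both other libraries numbered 114 in wild type, 940 in crwn1 and 1246 in crwn4. Pairs with at least 2 such neighbours, as a joined stretch of chromosome would give, numbered 0, 10 and 13. The limit of at least 10 counts was the same for each library, although depth differed. The variance over mean differed as well (1.14 in wild type, 3.22 in crwn1 and 5.15 in crwn4). These numbers therefore do not show that the mutant libraries hold more contacts of their own. Of the 10 in crwn1, 7 joined 24.9 to 25.3 Mb of chromosome 1 with 22.4 to 22.7 Mb of chromosome 3. All 13 in crwn4 joined a pericentromeric window with an arm window and held 12 to 49 read pairs.

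Loci in the chromosome arms that met each other across the nucleus were present in all 3 libraries. The rule set beforehand called 247 windows in 57 elements in wild type, of which 189 windows lay within 3 Mb of a chromosome end. Over 1275 pairs of these elements on different chromosomes, mean observed over expected was 1.3 in wild type (1.297 to 1.304), 1.24 in crwn1 (1.238 to 1.245) and 1.22 in crwn4 (1.216 to 1.225). Elements were called in wild type by the same measure, a choice that favours wild type. The ratios to wild type were 0.955 and 0.939. They were 1.08 and 1.11 with 50 kb windows, 1.05 and 1.09 at a threshold of 2, and 1.04 and 1.05 with elements called in crwn4, so the direction depended on the setting.

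A stricter local rule, added after the data were seen, called 23 windows in wild type, 21 in crwn1 and 119 in crwn4. Calls falling independently on the 984 arm windows would share 0.0594. Biases common to the libraries would also exceed that number, so it cannot separate them from contacts. All libraries shared 17 windows. They formed 9 loci: 7 to 7.1 Mb of chromosome 1; 1.9 to 2.1, 3 to 3.2, 16.6 to 16.8 and 22.5 to 22.7 Mb of chromosome 3; 11 to 11.3 and 15.5 to 15.6 Mb of chromosome 4; 4.7 to 4.9 and 10.2 to 10.4 Mb of chromosome 5. Over their 28 pairs on different chromosomes, observed over expected averaged 8.08 ± 5.72 in wild type, 6.13 ± 4.04 in crwn1 and 7.22 ± 4.93 in crwn4 (SD over pairs, which are parts of 1 library).

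The crwn1 library was lower than wild type in 27 of the 28 pairs, at 0.759 times the mean (0.735 to 0.784). The crwn4 library was lower in 20 pairs, at 0.894 times (0.861 to 0.928), but at 1.02 times with each 10 kb window pair counted once. The strongest pair in wild type joined 7 to 7.1 Mb of chromosome 1 with 22.5 to 22.7 Mb of chromosome 3, at 20.8 in wild type, 13.8 in crwn1 and 15.7 in crwn4. Mean contact of each locus with its partners was 0.704 to 0.843 times wild type in crwn1. In crwn4 it was 0.763 to 1.1 times, with the loci at 16.6 Mb of chromosome 3 (1.06) and 11 Mb of chromosome 4 (1.1) above wild type.

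**Figure D3:**
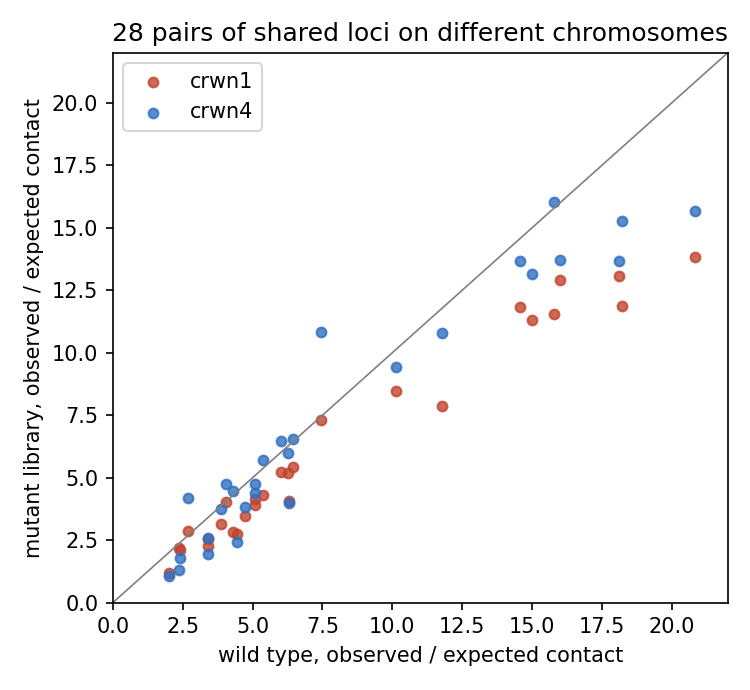
Observed over expected contact of the 28 pairs of shared loci on different chromosomes in crwn1 (red) and crwn4 (blue), on the vertical axis, against wild type on the horizontal axis; each point is 1 pair and the line marks equal values. In crwn1, 27 pairs lie below the line, and in crwn4, 20 pairs do.

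The 10 kb windows with the most contacts among these loci held genes of several kinds. At 1950001 to 1960000 of chromosome 3, with 985 read pairs in wild type, lay ATG8H (AT3G06420), an autophagy gene, and PPR2 (AT3G06430), which encodes a pentatricopeptide repeat protein. At 3130001 to 3140000 of the same chromosome (912 read pairs) lay RECA3 (AT3G10140), PAP16 (AT3G10150), a purple acid phosphatase gene, and DFC (AT3G10160). SEN1 (AT3G45590), a splicing endonuclease gene, TET3 (AT3G45600) and DOF6 (AT3G45610) lay at 16730001 to 16740000, and NTMC2T4 (AT3G61050), PP2-A13 (AT3G61060) and the peroxisome gene PEX11E (AT3G61070) at 22600001 to 22610000. On chromosome 4, the tubulin gene TUB9 (AT4G20890), MS5 (AT4G20900) and HEN1 (AT4G20910), a small RNA methyltransferase, lay at 11180001 to 11190000, and PANK2 (AT4G32180), ASY2 (AT4G32200) and AT4G32190 at 15540001 to 15550000. P5CR (AT5G14800), of proline synthesis, lay with AT5G14790 and the pseudogene AT5G14810 at 4780001 to 4790000 of chromosome 5. The windows at 7060001 to 7070000 of chromosome 1 (AT1G20380, AT1G20390) and 10350001 to 10360000 of chromosome 5 (AT5G28405, AT5G28410, AT5G28415) each held pseudogenes. Shared windows held 25.5 protein-coding genes and 3.41 pseudogenes on average, against 25.5 and 2.29 over arm windows, at the 46.1st and 83.7th percentile of 10000 random placements.

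Pericentromeres, which gather in chromocentres, met those of other chromosomes at 1.91 times the expected contact in wild type (1.91 to 1.92), 1.76 in crwn1 (1.75 to 1.77) and 2.21 in crwn4 (2.19 to 2.22). The crwn4 library was above wild type in 7 of 10 chromosome pairs and crwn1 in 3 of 10. Means over chromosome pairs were 1.94 ± 0.534, 1.77 ± 0.375 and 2.23 ± 0.347 (SD). The median window pair lay at 0.805 in wild type, 1.15 in crwn1 and 1.61 in crwn4. The direction depended on the setting. The crwn1 ratio to wild type was 1.03 with 50 kb windows, and the crwn4 ratio was 0.287 uncorrected, 0.996 with 200 kb windows and 0.933 with pericentromeres of 1 Mb each side. In wild type, 6 windows next to the centromeres were covered above 2 times the median, and 4.34% of wild-type read pairs touched them, against 1.38% in crwn1 and 1.58% in crwn4. Read pairs between these 6 windows made up 2.09% in wild type, but 0.0065% of its distinct 10 kb window pairs. The intervals above use the variance over mean between arms, so they may be too narrow for pericentromeres. Without the 6 windows, the ratio to wild type was 1.01 in crwn1 and 1.38 in crwn4. Over the 33 pericentromeric windows with at least 50% of the median coverage in all libraries, the ratios were 0.663 and 0.711. Observed over expected there was 10.3 in wild type, 6.82 in crwn1 and 7.31 in crwn4. By their coverage, at least 0.578 times the median in each library, the 6 windows are among the 33.

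The heterochromatic knob of chromosome 4 met pericentromeres of other chromosomes more in both mutant libraries. Observed over expected was 1.1 in wild type (1.07 to 1.14), 1.37 in crwn1 (1.33 to 1.41) and 1.71 in crwn4 (1.65 to 1.78). Both libraries were above wild type for each of the 4 partner chromosomes, with chromosome 2 the highest partner (1.68 in wild type, 2.34 in crwn1, 2.18 in crwn4). The smallest margin was that of chromosome 5 in crwn1 (1.04 in wild type, 1.05 in crwn1). Ratios to wild type were 1.24 (1.19 to 1.296) and 1.56 (1.48 to 1.63). Knob contacts with arms of other chromosomes were 0.798, 0.782 and 0.763. With windows under 50% of the median coverage left out, the crwn1 ratio was 0.788 and that of crwn4 was 1.16.

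**Figure D4:**
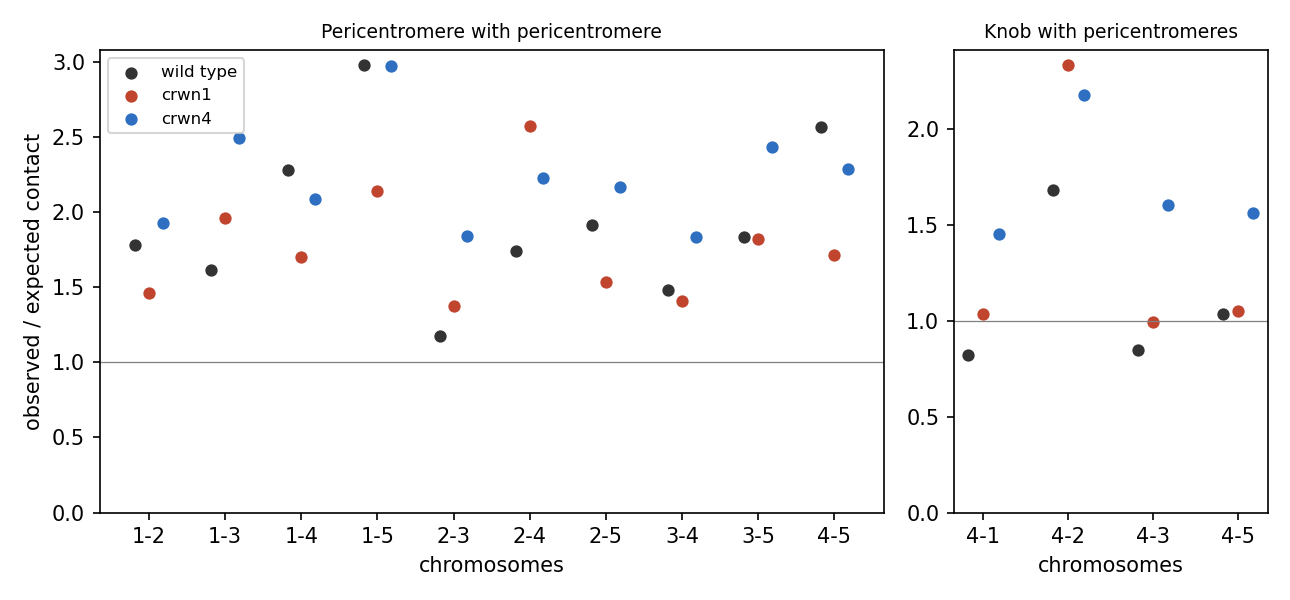
Observed over expected contact (vertical axis) per pair of chromosomes (horizontal axis) for pericentromeres with each other and for the chromosome 4 knob with pericentromeres, 1 point per library. For the knob, both mutant libraries lie above wild type in each of the 4 pairs; for pericentromeres, crwn4 does so in 7 of 10 and crwn1 in 3 of 10.

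Pericentromeres met arms of other chromosomes less often than arms met arms, at 0.566 in wild type (0.565 to 0.568), 0.593 in crwn1 (0.591 to 0.595) and 0.663 in crwn4 (0.661 to 0.666). The crwn4 library was above wild type in 10 of 10 chromosome pairs and crwn1 in 5 of 10. The crwn1 ratio to wild type, 1.05, was 0.984 without correction and 0.934 with windows under 50% of the median coverage left out, so its direction depended on the setting. Contact of a pericentromere with its own arms was 0.770 in wild type (0.767 to 0.772), 0.834 in crwn1 (0.831 to 0.836) and 0.711 in crwn4 (0.708 to 0.715). It was above wild type on 5 of 5 chromosomes in crwn1 and on 0 of 5 in crwn4. With windows under 50% of the median coverage left out, both were above wild type, at 1.13 and 1.02 times.

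Chromosome ends met each other at 5.13 times the expected contact in wild type (5.10 to 5.17), 4.83 in crwn1 (4.79 to 4.87) and 5.30 in crwn4 (5.25 to 5.35). For 25 pairs of ends away from the rDNA arrays the values were 6.68 ± 0.741, 6.47 ± 0.897 and 7.11 ± 0.850 (SD over pairs). An end next to rDNA with an end that is not gave 2.35 ± 0.606, 1.88 ± 0.433 and 1.86 ± 0.520 over 14 pairs. Both rDNA ends, the short arms of chromosomes 2 and 4, met at 5.44, 5.06 and 8.30. The crwn4 library was above wild type in 4 of 10 chromosome pairs and crwn1 in 2. The direction in crwn4 depended on the setting, with ratios to wild type of 1.03 for the mean, 0.988 for the median, 0.961 with square-root correction and 0.880 without correction.

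Contact decreased with distance in all 3 libraries. Decay exponents from 0.2 to 3 Mb were -0.590 ± 0.0167 in wild type, -0.568 ± 0.0196 in crwn1 and -0.589 ± 0.0236 in crwn4 (SD over 8 arms). The crwn1 slope was shallower than wild type in 8 of 8 arms, by 0.0216 ± 0.00486, and the crwn4 slope in 4 of 8, by 0.000147 ± 0.00744. The size depended on the range: from 0.1 to 1 Mb the slopes were shallower by 0.0901 in crwn1 and 0.0199 in crwn4. Counts within a chromosome made up 50.8% in wild type (50.8 to 50.8), 49.5% in crwn1 (49.5 to 49.5) and 47.3% in crwn4 (47.3 to 47.3). Without pairs within 1 Mb, crwn1 was no longer below wild type (37.63% and 37.56%), and crwn4 was at 35.1%.

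**Figure D5:**
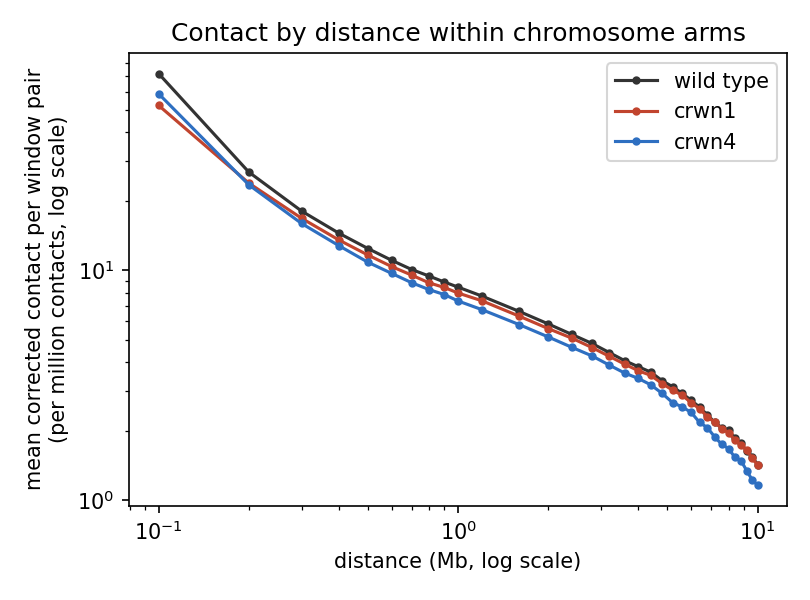
Mean corrected contact per pair of 100 kb windows (vertical axis, scaled to equal library totals, log scale) against distance within arms (horizontal axis, Mb, log scale), 1 line per library. Slopes from 0.2 to 3 Mb average -0.590 in wild type, -0.568 in crwn1 and -0.589 in crwn4.

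A larger share of contacts was long range, between chromosomes or over 2 Mb, in both mutant libraries. The median arm window had 71.0% in wild type, 74.5% in crwn1 and 75.1% in crwn4, with log2 changes of 0.07 and 0.08. All 984 arm windows were above wild type in crwn1 and 977 in crwn4. Pericentromeric windows differed more, with median log2 changes of 0.19 and 0.24, and 116 and 120 of 130 windows were above wild type. Windows at chromosome ends hardly differed, with medians of 84.2% in wild type, 84.3% in crwn1 and 85.0% in crwn4. Of these 50 windows, 32 in crwn1 and 36 in crwn4 were above wild type. The largest differences above wild type in crwn1 lay at 13.2 and 13 Mb of chromosome 3 and at 16 Mb of chromosome 1 (log2 0.43, 0.40 and 0.42). In crwn4 they lay at 13.9 and 13 Mb of chromosome 3 and 3.4 Mb of chromosome 4 (0.49, 0.41 and 0.44). The largest differences below wild type lay at 3 Mb of chromosome 4 and at 11.9 and 12 Mb of chromosome 5 in crwn1 (-0.25, -0.23 and -0.19). In crwn4 they were at 11.9 and 12 Mb of chromosome 5 (-0.15 and -0.07) and 3.6 Mb of chromosome 2 (-0.09). The microRNA gene MIR854e (AT5G05005), in the window at 11.9 Mb of chromosome 5, was the single gene with a symbol in these windows.

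Compartment signs of arm windows were those of wild type in 84.0% of 1016 windows in crwn1 (81.6 to 86.2) and 75.3% in crwn4 (72.5 to 77.9). The left arm of chromosome 1 shared 29.6% in crwn1, where the other arms shared 85% or more. In crwn4 the left arm of chromosome 5 shared 10.5%, the right arm of chromosome 4 65.6%, the left arm of chromosome 1 73.3% and the left arm of chromosome 2 76.2%. The sign of a whole arm depends on its orientation by gene number: with the sign set by the wild-type eigenvector, 89.4% and 83.5% of windows shared it. With uncorrected counts the signs were shared in 99.3% and 97.9% of windows.

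The 4 gene lists did not gather between chromosomes beyond random lists in wild type. The 30 developmental regulators that are repressed in most leaf cells had an observed over expected of 1.05 (0.929 to 1.19, percentile 44.9), the 16 seed storage and oleosin genes 0.984 (0.712 to 1.33, percentile 36.3), the 24 photosynthesis genes 1.09 (0.919 to 1.29, percentile 55.1) and the 16 housekeeping genes 1.05 (0.838 to 1.29, percentile 40.4). In crwn1, photosynthesis genes were at 0.840 (0.698 to 1.00), the 3.66th percentile and 0.770 times wild type (0.605 to 0.980). With 50 kb windows that ratio was 0.899. In crwn4 the same genes were at 1.12, the 69.2nd percentile and 1.02 times wild type. The low crwn1 value is 1 of many list percentiles, over 4 lists and 3 libraries. Seed storage genes were at 1.26 in crwn1 and 1.38 in crwn4, at the 85.8th and 90.5th percentiles, with ratios to wild type whose intervals spanned 1 (0.863 to 1.90 and 0.882 to 2.22). The intervals of the remaining list ratios, between chromosomes and within arms, also spanned 1. Within arms, percentiles ran from 34.7 to 62.0 in wild type, 8.71 to 90.1 in crwn1 and 21.9 to 91.9 in crwn4.

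Local contact density is the contact of a gene's 10 kb window with its surroundings. Its median over photosynthesis genes was 0.848 in wild type (24 genes), 1.01 in crwn1 (24) and 0.930 in crwn4 (23). LHCB1.1, LHCB1.2 and LHCB1.3 share 1 window, as do RBCS1B and RBCS2B, and each gene counts. Gene by gene, the median ratio to wild type was 1.04 in crwn1 and 1.01 in crwn4, not above the 1.05 and 1.02 over all protein-coding genes measured (26819 and 26800). GAPB (AT1G42970), a chloroplast glyceraldehyde phosphate dehydrogenase gene, had the highest wild-type density of the list at 1.6, and the light-harvesting gene LHCB4.1 (AT5G01530) the lowest at 0.541. LHCB4.1 (1.56 times wild type), PSBO1 (AT5G66570; 1.48) and LHCA2 (AT3G61470; 1.45) had the highest ratios in crwn1, and LHCA1 (AT3G54890; 1.49) did in crwn4. LHCB4.1, PSBO1 and LHCA2 were also the lowest of the list in wild type (0.541, 0.565 and 0.674). The SD over the list was 0.281 in wild type, 0.165 in crwn1 and 0.237 in crwn4. High ratios at genes that are extreme in wild type are therefore not read as changes of those genes. Counting intervals in crwn1 lay above those in wild type for LHCB4.1 and LHCA2, and overlapped for PSBO1. LHCA1 was not among the lowest 3 in wild type, so this reason does not cover it. Its interval was 0.661 to 0.827 in wild type and 0.954 to 1.27 in crwn4. LHCA1 was picked as the highest crwn4 ratio of its list, and its difference was not tested further.

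Among developmental regulators the median density was 0.934, 0.983 and 0.930 in wild type, crwn1 and crwn4. The meristem gene KNAT1 (AT4G08150; 1.44), LEC1 (AT1G21970; 1.32) and the ovule identity gene STK (AT4G09960; 1.245) were highest in wild type, and MAF5 (AT5G65080; 0.730), SHP1 (AT3G58780; 0.736) and SEP2 (AT3G02310; 0.737) were lowest. The floral gene PI (AT5G20240) was at 1.36 times wild type in crwn1 and STM (AT1G62360) at 0.750 times. AG (AT4G18960) was at 1.2 and AP1 (AT1G69120) at 0.678 times wild type in crwn4. Seed storage genes lay at 0.886, 0.920 and 0.902, with CRU2 (AT1G03890) lowest in wild type at 0.639 and CRA1 (AT5G44120), a cruciferin gene, at 0.732 times wild type in crwn1 and 0.770 times in crwn4. Housekeeping genes lay at 0.869, 0.938 and 0.943. UBQ10 (AT4G05320) was highest at 1.56 in wild type and at 0.686 times that in crwn4, and UBC9 (AT4G27960), lowest at 0.594, was at 1.31 times that. In each of the 4 lists the SD over genes was lower in both mutant libraries than in wild type, such as 0.105 in crwn1 against 0.191 for developmental regulators. For PI, STM, AG, AP1, CRA1, UBQ10 and UBC9, the counting intervals in the mutant libraries named overlapped those in wild type. Overlap does not show that a difference lies within counting error, and intervals of the single-gene ratios were not computed. For CRA1 in crwn1 the overlap was narrow, with an upper bound of 0.870 against a lower bound of 0.867 in wild type. For CRU2, the crwn1 interval (0.776 to 1.01) lay above that of wild type (0.561 to 0.725). At CRWN4, density was 0.729 in wild type (0.635 to 0.832), 0.8 in crwn1 (0.677 to 0.938) and 0.555 in crwn4 (0.425 to 0.711); at CRWN1 it was 1.12 (1.03 to 1.23), 1.19 (1.06 to 1.32) and 1.06 (0.929 to 1.21).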

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

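The comparisons were planned, but all tests of explanations here were chosen after the patterns they bear on had been seen; at CRWN1, the limits for a rearrangement and for repeated read pairs were written before the values of these tests were seen.

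Repeated counts, a property of the files outside the comparisons, were above the wild-type library in both mutants: a listed pair of 10 kb arm windows on different chromosomes held 2.37 counts in crwn1 and 3.51 in crwn4, against 1.13 in wild type. Deeper sequencing of independent read pairs is argued against, since variance over mean was at least 3.22 in the mutants. Unequal expected counts of window pairs also raise this value, and their part was not separated. Copies of the same ligated fragment stay open and may be the source: variance over mean was nearly the same with 100 kb as with 10 kb windows (ratio 1.21 in crwn1 and 1.14 in crwn4), although the mean count was far higher. The limits of that test were set after first values had been seen, and the ratio in wild type, with few repeats, was 1.301. Whether copies were removed in wild type alone is not given in the sources used here. The crwn4 library, with 7094831 read pairs after division by this variance, has the least information of the 3.

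The window of CRWN1 met the chromosome 3 locus and pericentromeres in the crwn1 library. Repeated read pairs are argued against, since with each 10 kb pair counted once contact in crwn1 was still 6.05 times the higher other library. A reciprocal translocation is argued against by the quadrants around the contact, whose opposite pairs differed 1.02 times, a test added once the contact strength had decided nothing. For chance among windows, a count used the locus named beforehand: the window of CRWN1 took part in 8 pairs of the rearrangement search in crwn1, against a median of 1, and 0.508% of arm windows (5 of 984, CRWN1 included) had as many. Such windows were thus rare. The count was chosen after the contact was seen and includes its pairs with the chromosome 3 locus, so it cannot decide about chance by itself. Another rearrangement, such as a copy of the chromosome 3 sequence inserted at CRWN1, stays open, because the highest contact was 0.601 times that of windows 0.5 Mb apart on a chromosome. The biological alternative is that the altered crwn1-1 allele, known as a T-DNA insertion, is itself drawn to this locus; with 1 library per genotype the allele, the background of the line and the library cannot be told apart.

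Pericentromeres of different chromosomes met more in crwn4 than in wild type by the mean in the main setting. Some alternatives turned this direction, such as uncorrected counts (ratio 0.287) and 200 kb windows (0.996). Random ligation, which pulls values toward 1, is argued against by a median of 1.61 in crwn4. Windows of low coverage could carry the difference: over windows with at least 50% of the median coverage in all libraries the ratio was 0.711, the other way. The 6 windows of very high coverage are among these and weigh more in so small a set, so this ratio does not test low coverage alone. With the filter and without the 6 windows the ratio was 0.482, over windows that differed between libraries. Repeated read pairs stay undecided: counting each 10 kb pair once lowered wild type (1.91 to 1.36) more than crwn4 (2.21 to 2.07), which raises the ratio by itself, so its value of 1.62 with the 6 windows of very high coverage left out tests nothing. These 6 windows stay undecided as well: read pairs between them made up 2.09% in wild type and 0.342% in crwn4, so leaving them out had to raise the ratio, and its value of 1.38 tests nothing. Genotype stays open as well and is untested, with 1 library each.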

How the results depend on the processing

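Counting each 10 kb pair once, leaving out windows of very high coverage, medians, combinations of these, local contrast and the eigenvector sign were chosen after seeing the data, as were all alternatives for the shared loci and the CRWN1 window. Of 261 alternative values over 42 results, 132 stayed within the interval of the main value and 100 moved beyond it. The remaining 29 lay on the other side of no change where the main interval excluded no change. Those that moved stayed on the same side, except that cis share and compartment agreement have no such side and count only as within or beyond. Of the 132, 14 also lay on the other side, for gene lists and the crwn4 decay difference, whose main intervals held no change. The CRWN1 contact (ratios 5.76 to 11.03) and the knob ratio in crwn4 (1.16 to 1.77) kept their direction in each alternative, and the gene list ratios stayed in their intervals, some of them on the other side of 1. The cause was not tested except where stated. Pericentromere contact between chromosomes, as a ratio to wild type in crwn1 and crwn4, was 0.922 and 1.15. It was 0.236 and 0.287 uncorrected, 0.829 and 1.01 with square-root correction, 1.03 and 1.28 with 50 kb windows, 0.840 and 0.996 with 200 kb windows, 0.290 and 0.505 with windows under 50% coverage left out, 0.780 and 0.933 within 1 Mb, 1.01 and 1.31 within 2 Mb, 1.17 and 1.52 with pairs counted once, and 1.43 and 2.01 as medians. Without the windows of very high coverage it was 1.01 and 1.38, then 1.21 and 1.62 with pairs counted once, 1.15 and 1.45 uncorrected, 0.996 and 1.36 with square-root correction, 0.848 and 1.12 within 1 Mb and 0.292 and 0.482 with the coverage filter. That filter left 41, 64 and 42 of 150 pericentromeric windows in wild type, crwn1 and crwn4. Pericentromere to arm contact between chromosomes was 0.984 and 1.03 uncorrected, 1.07 and 1.18 with square-root correction, 1.06 and 1.18 with 200 kb windows, 0.934 and 1.13 with the coverage filter, 1.08 and 1.24 within 1 Mb, 1.03 and 1.099 within 2 Mb, 1.00 (0.9999) and 1.07 with pairs counted once, 1.04 and 1.16 without very high windows, 1.04 and 1.07 as medians, and 1.16 in crwn4 with 50 kb windows. Within chromosomes it was 1.101 and 0.897 uncorrected, 1.102 and 0.936 with square-root correction, 1.13 and 1.02 with the filter, 1.13 and 0.946 within 1 Mb, 1.05 and 0.914 within 2 Mb; crwn1 had 1.09 with 200 kb windows and 1.09 as median, and crwn4 0.917 with 50 kb windows. Telomere contact was 0.773 and 0.880 uncorrected, 0.877 and 0.961 with square-root correction and 0.896 and 1.15 with pairs counted once; in crwn4 it was 0.998 with the filter and 0.988 as median. Knob contact was 1.12 and 1.44 with 200 kb windows, 0.788 and 1.16 with the filter and 1.36 and 1.77 as medians; in crwn1 it was 1.35 uncorrected and 1.32 with square-root correction. Element contact was 0.993 and 1.02 uncorrected, 1.08 and 1.11 with 50 kb windows, 0.909 and 0.956 with 200 kb windows, 0.934 and 0.931 with the filter, 0.925 and 0.985 with pairs counted once, 1.05 and 1.09 at a threshold of 2, 0.906 and 0.943 at 3, 0.967 and 0.948 with 3 partner loci, 0.941 and 0.930 when called in crwn1, and 1.04 and 1.05 when called in crwn4; crwn1 had 0.933 with square-root correction and 0.959 when thinned. The number of elements ran from 19 with 200 kb windows to 161 with 50 kb windows, against 57. Shared loci had 0.713 and 0.859 uncorrected and 0.787 and 0.931 as local contrast, and crwn4 1.02 with pairs counted once. The decay difference was 0.0901 and 0.0199 from 0.1 to 1 Mb, and 0.0152 uncorrected in crwn1. The cis share in wild type, crwn1 and crwn4 was 37.6%, 37.6% and 35.1% without pairs within 1 Mb, 55.9%, 52.7% and 51.3% with 10 kb windows, and 52.2%, 49.3% and 47.7% without pericentromeres. Compartment agreement was 99.3% and 97.9% uncorrected, 89.4% and 83.5% with the sign set by wild type, and 80.5% in crwn1 with 50 kb windows. Long-range log2 change in arms was 0.10 and 0.14 beyond 5 Mb and 0.0549 and 0.0705 with 200 kb windows; in pericentromeres it was 0.16 and 0.22 with 200 kb windows and 0.33 in crwn4 beyond 5 Mb. Depth limits the gene lists, with 49 to 1056 read pairs between chromosomes per list, and the CRWN1 contact, with 13 read pairs in wild type and 16 in crwn4. Gene lists were not run on thinned counts.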
